A study of Danio rerio with 3 samples.

How the data were processed

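Single cells of adult zebrafish hearts were profiled by droplet RNA sequencing (10x Chromium) before injury (day 0) and 3 and 7 days after chemical ablation of ventricular cardiomyocytes. Each day had 1 library, made from 6 hearts that were digested in 2 sets of 3 and pooled before capture, with 2600 cells loaded per library. Injured fish had received 5 mM metronidazole for 48 hours, which kills cells carrying the bacterial nitroreductase of the ablation transgene. The labels list no metronidazole for day 0, so effects of the drug itself cannot be told apart from those of the injury. The labels give the strain as AB and do not say which transgenic line was used for these libraries. The submitters' processing notes name Cell Ranger and the genome build GRCz10. The version of Cell Ranger and the normalization tool are not given in the sources used here.

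The deposited expression table held natural log (ln) values for 26320 genes in 754 cells. The deposited metadata gave, per the file headers, counts of UMIs and counts of detected genes per cell, a mitochondrial percent, the day of each cell and cluster numbers at 2 resolutions. The mitochondrial percent column as deposited was 0 in every cell, although the table holds 13 mitochondrial-encoded genes with counts, so that column was not used and the percent was computed from those genes. Reversing the logarithm gave values that summed to 10000 per cell. Multiplied by the deposited UMI count of the cell, all 497895 values above 0 lay within 0.001 of a whole number, and the largest distance was 0.000479. The recovered totals equalled the deposited UMI counts in 754 of 754 cells, and the numbers of genes above 0 equalled the deposited gene counts in 754 of 754 cells. The recovered UMI counts were used throughout. At least 1 UMI was found for 14041 genes, and 16196 symbols of the table matched a current zebrafish name table. Gene names are printed as deposited. Positions on GRCz10 were not analysed here.

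All deposited cells were used: 272 at day 0, 114 at day 3 and 368 at day 7. The labels state a recovery of 272, 141 and 368 cells. The fewest UMIs in any deposited cell were 2004, which points to a minimum applied before deposit. No doublet caller was run, and the labels do not say whether doublets were removed.

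The 7 clusters of the finer deposited resolution carried numbers without names. They were named by marker lists fixed before the data were examined, and a cluster could not take a name if more markers of another class than of its own stood among its 10 leading genes by fold. Leading genes were ranked among genes detected in at least 25% of the cluster's cells, a limit chosen after seeing the data. Without it, the 10 leading genes of cluster 0 held the globin genes zgc:92880, si:xx-by187g17.1, hbaa1, ba1 and ba1l, 3 of them erythroid markers. These globin genes were detected in at most 9.96% of the cells of any cluster, and 2 cells had over 10% of their UMIs from globin genes. Clusters 0, 2, 3 and 6 were named endothelial or endocardial-like, cluster 1 mural-like, cluster 4 fibroblast or mesenchymal-like and cluster 5 cardiomyocyte-like, which gives 4 classes. None of the 10 leading genes of any cluster was a marker of another class. Clusters 0 and 3 had no endothelial marker among their 10 leading genes and were named from their marker sums, with 18 and 16 endothelial markers detected. Their summed endothelial marker levels were 11750.5 and 8121 CPM, against 456 and 437 for mural and 1154 and 1644 for fibroblast markers. Summed cardiomyocyte marker levels were 11871 CPM in cluster 0 and 17331 in cluster 2, above their endothelial sums of 11750.5 and 14741, and 132230.5 in cluster 5. The highest sum alone would thus have named both clusters cardiomyocyte. They were kept as endothelial-like, after the data were seen, because their cardiomyocyte sums lay far below that of cluster 5 and their endothelial sums far above its 3122. Cluster 3 led with stress-related genes, among them hsp90b1 and nppb.

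Levels are summed UMIs of a library or of a class within a library, scaled to a summed total of 1000000 (CPM), with exact Poisson intervals at 95%. Folds are plain ratios of these levels with exact intervals for a ratio of 2 counts. Where a group had 0 UMIs, the fold is given as at least the ratio to 3 counts in that group. This value leaves out the counting error of the other group, so it is not the lower end of a 95% interval, which can lie lower. Log2 ratios carry a pseudocount of 10 CPM in both groups. Shares of cells have exact Clopper-Pearson intervals at 95%, and a share of 0 is given with the share that 3 cells would make. Intervals of levels and folds treat UMIs as independent and leave out the variation between cells. All intervals cover counting error only, since 1 library per day leaves the variation between fish, hearts and libraries unmeasured. For this reason there are no p-values and no counts of changed genes.

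Comparisons of day 3 with day 0, day 7 with day 0 and day 7 with day 3 were made over all cells and within classes with at least 20 cells in both libraries. Within classes this allowed the endothelial class on all days and the mural class at day 7 and day 0. Genes were named by a rule fixed before the data were examined. Among genes detected in at least 10% of the cells of 1 of the libraries and in at least 5 cells, these were the 10 with the highest and the 10 with the lowest log2 ratio. Added to these were up to 2 members in each direction of each gene list described, and a fixed set of genes of amino acid transport, mTOR signalling, cardiomyocytes, matrix, macrophages and the cell cycle. Since several of the named genes held most of their UMIs in 1 cell, the ratio without the cell richest in that gene in each library was added after seeing the data, and genes ranked highest or lowest that way may also be named. Results for some genes are not reported here.

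For each of 26 gene lists fixed before the data were examined, members detected in at least 5 cells counted as measured. The median log2 ratio of the measured members was placed among 10000 random lists of the same size, matched over 20 bins of mean expression. The percentile is a description of these libraries, not a test. Over all measured genes the median log2 ratio in the endothelial class was -0.04 for day 3 against day 0, -0.10 for day 7 against day 0 and -0.05 for day 7 against day 3. A further 13 lists held markers of cell types and of cycling cells. For shares of cells with a UMI, every cell was thinned to 2000 UMIs, which left out no cell.

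Both steps were tested on simulated data, in which counts were drawn at the depth of each library from the pooled profile of a class and known changes were put into 200 genes. Over the 4 comparisons within classes, simulated log2 changes of -2 came out at medians of -2.02 to -1.90, those of -1 at -1.14 to -0.76, those of 1 at 0.82 to 0.99 and those of 2 at 1.75 to 1.92. In the same simulations the intervals held the true ratio for 96.1% to 97.0% of genes, and 2.5% to 4.5% of 200 lists with no change lay outside the central 95% of random lists. Each simulated count was 1 Poisson draw per gene and library, so UMIs were not clumped in single cells as in these data. The coverage therefore need not hold for genes with many UMIs in 1 cell.

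Alternatives fixed in advance were pseudocounts of 1 and 50 CPM, the mean over cells in place of the sum, totals without globin or mitochondrial-encoded genes, no erythroid cells, thinned cells, equal weight for each class, other detection filters, list sums in place of medians, classes by the highest marker score, and other definitions of cycling cells. Added after seeing the data were the coarser clusters, the results without the richest cell of each gene or without the deepest day 3 cell, and the cycling markers found in few cells. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.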

Results

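The series asked how the cells of the adult zebrafish heart respond to loss of ventricular cardiomyocytes, in a study of amino acids and mTOR signalling in heart regeneration. It held 3 single-cell libraries, 1 each for uninjured hearts (day 0) and for hearts 3 and 7 days after injury. There were 272 cells with 857410 UMIs at day 0, 114 cells with 493660 UMIs at day 3 and 368 cells with 1355246 UMIs at day 7. Median UMIs per cell were 2677, 3260.5 and 3124.5, with ranges of 2005 to 9831, 2004 to 31129 and 2005 to 15553. Median genes per cell were 612, 685.5 and 573.5. The deepest day 3 cell held 6.31% of that library's UMIs. Levels are in CPM, UMIs scaled to a total of 1000000. No value had replicates, and every interval covers counting error only.

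The cell types recovered differed between the 3 days. Endothelial or endocardial-like cells, which line the chambers and vessels, made up 61.0% of cells at day 0 (166 of 272, interval 55.0 to 66.9), 99.1% at day 3 (113 of 114, 95.2 to 100) and 60.9% at day 7 (224 of 368, 55.7 to 65.9). Mural-like cells, the contractile cells of vessel walls, were 32.4% at day 0 (26.8 to 38.3), 0 of 114 at day 3, which allows a share of up to 2.63%, and 16.6% at day 7 (12.9 to 20.8). Cardiomyocyte-like cells were 6.62% at day 0 (3.97 to 10.3), 0 of 114 at day 3 and 8.15% at day 7 (5.57 to 11.4). Fibroblast or mesenchymal-like cells were 0 of 272 at day 0, which allows up to 1.1%, 0.877% at day 3 (1 cell, 0.0222 to 4.79) and 14.4% at day 7 (53 cells, 11 to 18.4). That last class consisted almost wholly of day 7 cells, so it may be a feature of that library as much as a cell type. These shares describe cells that survived digestion, capture and the depth minimum, in 1 library per day. With each cell assigned to its highest marker score instead, the endothelial shares were 30.9%, 31.6% and 17.7%. By that score 30 of the 114 day 3 cells were highest for macrophage markers and 16 for epicardial markers. The score averages the scaled levels of a list's markers, so a few UMIs of rare markers can decide it. It placed 0, 2 and 8 cells at day 0, 3 and 7 as B cells, although B cell markers had 0 UMIs. Marker scores here and below therefore do not settle what a cell is.

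**Figure D1:**
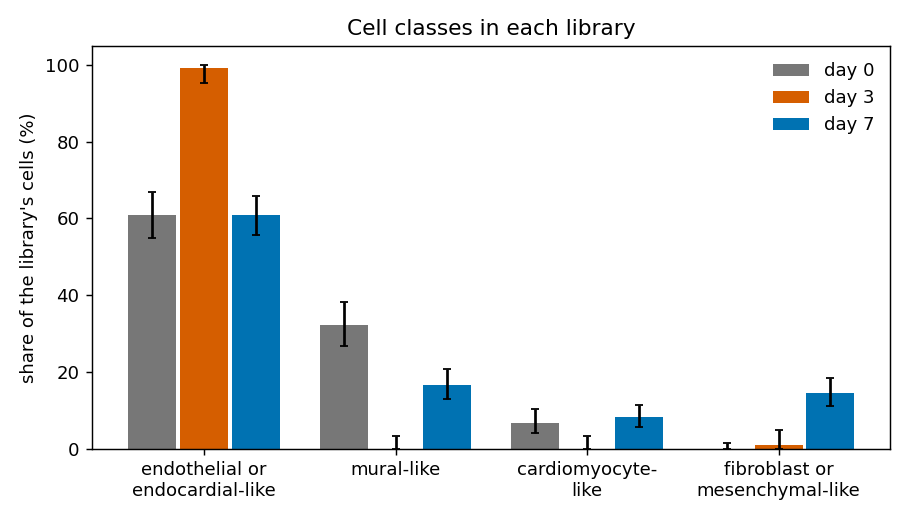
Percent of cells in each of the 4 classes at day 0, 3 and 7, with exact binomial 95% intervals and 1 library per day. The endothelial class stands at 99.1% at day 3 against 61.0% and 60.9% on the other days.

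Markers of T or NK cells, B cells and neural cells were sparse. Summed over all cells, T or NK cell markers gave 4, 1 and 13 UMIs at day 0, 3 and 7, B cell markers 0 UMIs on each day, and Schwann or neural markers 1, 6 and 6 UMIs. Macrophage or monocyte markers stood at 336, 891 and 243 CPM, most of them from the invariant chain genes cd74a and cd74b and the granulin genes, while mpeg1.1 had 0, 1 and 1 UMIs. Neutrophil markers stood at 1208, 1631 and 771 CPM, nearly all from srgn, which other blood and endothelial cells also express. Thrombocyte markers gave 89.8, 87.1 and 213 CPM. Epicardial markers stood at 1095, 2992 and 1146 CPM, and the keratin gene krt15 gave 2457 of the day 3 level. Erythroid markers were at 2071, 46.6 and 511 CPM, which reflected 1 globin-rich cell at day 0 and 1 at day 7.

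Cardiomyocyte transcripts were found in all classes. At day 0 the cardiac myosin light chain gene myl7 was detected in 97.7% of mural cells (median 2950.5 UMIs) and 99.4% of endothelial cells (median 2587 UMIs), after thinning. At day 3 it was detected in 63.7% of endothelial cells (interval 54.1 to 72.6), and at day 7 in 96.0% of endothelial and 98.4% of mural cells. Its level in endothelial cells was 9840.1 CPM at day 0, 639.8 at day 3 and 4087 at day 7, beside 66585 and 44419 in the cardiomyocyte-like cells of day 0 and day 7. In mural cells it was 1888 at day 0 and 1575 at day 7. At day 0 other cardiomyocyte genes were also higher in endothelial than in mural cells, with cmlc1 at 4870.0 against 911 and actc1a at 958 against 79.8. By marker score, 31 of the 166 endothelial cells of day 0 were highest for cardiomyocyte markers. Free RNA, doublets and misplaced cells were not told apart, and levels of cardiomyocyte genes in other classes are not read as expression by those cells.

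At day 3 after injury, cells of the endothelial class held far more RNA for a cardiac stress hormone than at day 0. The level of nppb, which encodes natriuretic peptide B, was 2136 CPM in 113 cells at day 3 against 33.4 in 166 cells at day 0, 64.0-fold higher (interval 39.8 to 110.3). Levels of nppb in the other classes are not given here, and the source of its RNA in this class was not determined for day 3 or day 7. The retinol carrier gene rbp4 was at 1813 against 68.7 (26.4-fold, 18.8 to 38.1), and zgc:158463, which has no assigned name, at 10233 against 568 (18.0-fold, 16.0 to 20.4). Among the 10 highest log2 ratios were also 3 her4 genes, which encode Hes-type repressors that Notch signalling switches on: her4.2 was higher by 30.6-fold (17.3 to 59.8), her4.4 by 33.3-fold (14.0 to 104) and her4.1 by 20.4-fold (12.9 to 34.2). In mural cells of day 0 the level of her4.1 was 1855 CPM, beside 760.4 in endothelial cells of day 3. Also among the 10 highest log2 ratios were the apelin receptor gene aplnra (4.65), the peptidase gene dpp7 (4.54) and the proteasome subunit gene psma6b (4.53). Most UMIs of these last 3 came from 1 day 3 cell each, and without it the log2 ratios were 3.47, 1.22 and 1.32.

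Transcripts of heart muscle stood lowest in endothelial cells at day 3 relative to day 0. The 10 lowest log2 ratios included the creatine kinase gene ckma (-4.50), gapdh (-4.46), the cardiac actin gene actc1a (-4.44), the fatty acid carrier gene fabp3 (-3.93), myl7 (-3.92) and the myosin light chain gene cmlc1 (-3.72). These are genes abundant in cardiomyocytes, and the source of their transcripts in this class was not determined. Among the rest, mhc1uba, an MHC class I gene, was at 26.6 against 399 CPM, 15.0-fold lower. The 1 further gene was uncharacterised. The ratios of the mitochondrial import gene timm8a (-3.52) and of si:ch211-281l24.3 (-3.45) rested on 1 day 0 cell each, and were -0.90 and -1.31 without it. Most day 0 endothelial cells came from clusters 0 and 2 (72 and 86 cells) and most day 3 cells from clusters 3 and 6 (60 and 34 cells). Among the leading genes of cluster 3 were nppb, lepb, psma2 and hsp90b1, and among those of cluster 6 aplnra, arl5c, klf2a and errfi1, so these ratios compare endothelial states as well as days.

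Proteasome, chaperone and ribosome biogenesis genes were higher in endothelial cells at day 3. With 1 library per day, the injury, the drug and the digestion or capture of a library cannot be told apart for these lists or those below. Of 39 measured proteasome genes, 36 were higher and 3 lower, with a median log2 ratio of 0.82 at percentile 100 of matched random lists. Among them psma2 stood at 1081 against 96.2 CPM. Heat shock and chaperone genes were higher in 33 of 42 cases (median 0.45, percentile 99.9), including hsp70.1 at 4518 against 1084 (4.17-fold, 3.79 to 4.58) and dnajb1b with a log2 ratio of 1.90. Ribosome biogenesis genes were higher in 32 of 40 cases (median 0.38, percentile 99.8), including the growth-promoting transcription factor gene mycb (log2 ratio 3.63) and nop56 (1.51). Translation factors had a median of 0.19 (percentile 96.7, 39 of 57 higher), which was 0.29 (percentile 99.4) without the richest cell of each gene, and ribosomal proteins one of 0.23 (percentile 87.6).

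Inflammation and immediate early genes had medians above those of random lists at day 3. The inflammation list had 12 of 20 members higher (median 0.71, percentile 100). The myeloid growth factor gene il34 was at 139 against 7.85 CPM, and the chemokine gene cxcl12a had 31 UMIs against 0, at least 10.8-fold higher. In the same libraries the macrophage marker sum was 891 against 336, and 191 of the 257 day 3 UMIs of cd74b lay in 1 cell. Immediate early genes were higher in 21 of 34 cases (median 0.49, percentile 99.7). The leptin gene lepb, which marks regenerating zebrafish tissue, had 44 UMIs against 0, at least 15.3-fold higher. Lower at day 3 were the hypoxia factor gene epas1b (log2 ratio -3.15) and the repressor gene her6 (-1.65).

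Transcripts encoded by the mitochondrial genome were lower after injury. All 13 were lower in endothelial cells at day 3 (median -1.51, percentile 0), with mt-nd4 at 967 against 4405 CPM. They made up a median of 2.04% of the UMIs of an endothelial cell at day 0, 0.762% at day 3 and 0.603% at day 7. Nuclear-encoded genes of oxidative phosphorylation were lower in 57 of 79 cases at day 3 (median -0.34, percentile 1.41), and sarcomere genes in 21 of 23 (median -2.0, percentile 0). Such oxidative phosphorylation genes, among them ndufc2, ndufv1 and cox5b2, were also among the leading genes of the cardiomyocyte-like cluster. Their lower level was not separated from that of cardiomyocyte RNA in this class.

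The amino acid and mTOR genes that motivated the study were sparsely counted. Of 49 listed mTORC1 pathway genes, 22 were measured in endothelial cells, and 16 were lower and 6 higher at day 3 (median -0.37, percentile 6.04). The list mixes genes that promote mTORC1 with genes that inhibit it, and RNA levels do not measure mTORC1 activity. Its median therefore gives no direction for the pathway, on any day. Transcripts of sesn1, a stress-induced inhibitor of mTORC1, were at 24.5 against 84.4 CPM (log2 ratio -1.45), and those of LAMTOR4, part of the complex that docks mTORC1 on lysosomes, had a log2 ratio of -1.46, which was -0.71 without 1 cell. The translation repressor gene eif4ebp1, whose product mTORC1 inactivates, had a log2 ratio of -0.33 (-0.70 to 0.00), and eif4ebp3l one of -0.35 (-0.93 to 0.16). Only 10 of 60 amino acid transporter genes were measured, 5 higher and 5 lower (median -0.08, percentile 50.8), and the median was 0.32 (percentile 95.1) without the richest cell of each gene. Amino acid synthesis and ATF4 target genes had 11 of 16 members higher (median 0.38, percentile 97.7), with cebpb, a stress-induced transcription factor, at a log2 ratio of 2.86. Without the richest cell of each gene that median was 0.23 at percentile 89.2. A glutamine synthetase gene, glula, had 16 UMIs against 1 (16.7-fold, 2.59 to 698). A second such gene, glulb, had 572 UMIs over all cells, 115 of them in 1 day 0 cell, and its ratio is not given here. The ratio of glula therefore does not stand for glutamine synthetase RNA as a whole.

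For the remaining lists in endothelial cells at day 3, medians were 0.12 for glutamine and branched-chain amino acid metabolism (percentile 81.3), 0.03 for aminoacyl-tRNA synthetases, 0.02 for glycolysis, -0.14 for the TCA cycle and fatty acid oxidation, 0.16 for cardiac stress genes, -0.01 for extracellular matrix (1.89 for its summed level), 0.14 for interferon response, 0.08 for the Wnt pathway, -0.12 for regeneration signals, -0.30 for apoptosis and -0.38 for the hypoxia response. Without the richest cell of each gene they were 0.35 (percentile 96.8) for glutamine and branched-chain amino acid metabolism, 0.26 (percentile 87.1) for aminoacyl-tRNA synthetases, 0.29 for cardiac stress genes and 0.07 for regeneration signals. Lysosome and autophagy genes had a median of 0.22 (percentile 97.0), which became 0.04 (percentile 69.4) without the richest cell of each gene. Antigen presentation genes stood at -0.78 (percentile 3.77) over 9 members, and at -0.47 (percentile 11.2) without the richest cell of each gene.

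**Figure D2:**
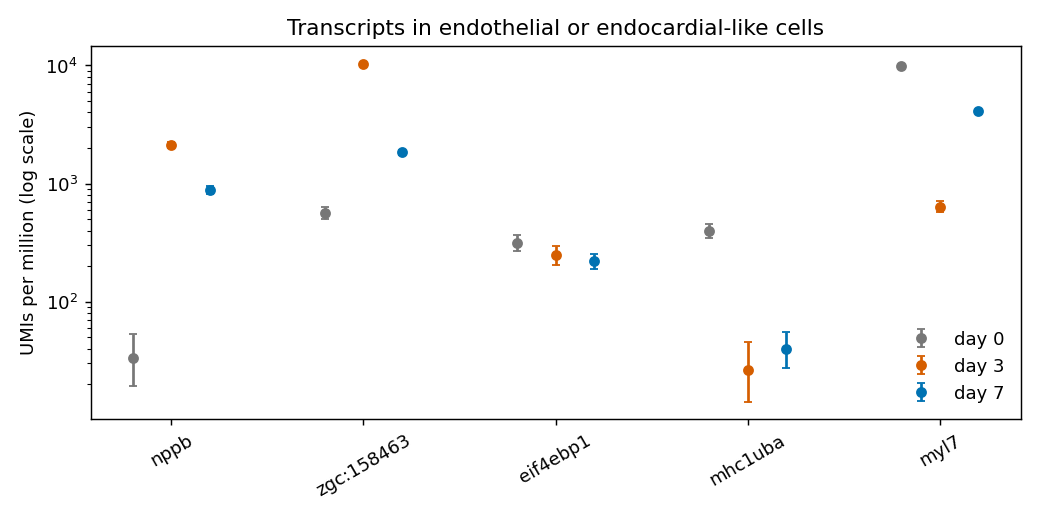
Level of 5 genes in endothelial cells at day 0, 3 and 7, in CPM on a log axis, with exact Poisson 95% intervals. The levels of nppb stand at 33.4, 2136 and 884, and those of myl7, a cardiomyocyte gene, at 9840.1, 639.8 and 4087.

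At day 7 after injury, endothelial cells still held more nppb RNA than before injury, and more RNA of extracellular matrix genes. The level of nppb was 884 CPM in 224 cells at day 7 against 33.4 at day 0 (26.5-fold, 16.4 to 45.7). Matrix genes were higher in 25 of 37 cases (median 0.41, percentile 100). The periostin gene postnb had 48 UMIs against 0, at least 9.80-fold higher. Collagen I gene col1a1b was at 381 against 90.3 CPM (4.22-fold, 3.09 to 5.89) and the fibronectin gene fn1b at 61.4 against 19.6 (3.12-fold, 1.57 to 6.90). These 3 genes were also abundant in the fibroblast-like cells found almost only in the day 7 library. By marker score, 31 of the 224 day 7 cells of the endothelial class were highest for fibroblast markers, against 3 of 166 at day 0, and the matrix ratios were not separated from these cells.

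Genes of antigen presentation were lower in endothelial cells at day 7, in 8 of 9 cases (median -1.25, percentile 0.14). For mhc1uba levels were 39.7 against 399 CPM, 10.0-fold lower, and for cd74a, the MHC class II invariant chain, 34.9 against 265, 7.60-fold lower. The uncharacterised si:zfos-2070c2.4 had the lowest log2 ratio (-3.48). Mitochondrial-encoded transcripts were lower in 13 of 13 cases (median -1.94, percentile 0.01). Immediate early genes were lower in 25 of 36 (median -0.51, percentile 0.29), and the cytokine inhibitor gene socs3a had a log2 ratio of -1.59. Heat shock and chaperone genes were lower in 30 of 42 (median -0.39, percentile 1.55), with hsp70.2 at -1.54, but the median was -0.27 (percentile 6.73) without the richest cell of each gene and the summed level of the list gave 0.0640. Proteasome genes were higher in 22 of 39 cases (median 0.09, percentile 98.5), and the mean over cells gave -0.00708. Translation factors had a median of 0.16 (percentile 99.8).

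Many other genes with extreme ratios at day 7 had most of their UMIs in single cells. Over 50% of the higher library's UMIs lay in 1 cell for 8 of the 10 highest and 6 of the 10 lowest genes. Higher genes of this kind, with the log2 ratio without that cell after it, were ccdc80 (4.09 and 2.11), chd3 (3.37 and 0.99), rwdd1 (3.34 and 1.51), her4.1 (3.33 and 0.17), gamt (3.24 and 0.71), h1f0 (3.00 and 1.21), uqcrc2b (2.93 and 0.12) and hsp90b1 (2.92 and 0.47). Lower genes were si:dkey-100n23.4 (-3.38 and -0.69), tmem256 (-3.33 and -1.43), si:ch211-281l24.3 (-3.19 and -1.03), puf60b (-3.17 and -0.54), timm8a (-3.15 and -0.53) and puf60a (-2.79 and -0.64), beside USMG5 (-2.88 and -2.10). Genes that ranked high without their richest cell were si:dkey-153m14.1 (2.73) and mustn1a (2.21), a gene of muscle and cartilage. At day 7, 193 of the 224 endothelial cells lay in cluster 0, against 72 of 166 at day 0.

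Genes of the mTORC1 pathway list, promoting and inhibiting ones together, were lower in endothelial cells at day 7 in 15 of 22 cases (median -0.53, percentile 0.30). The summed level of the list gave 0.0386, and neither value measures mTORC1 activity. The sestrin gene sesn3, whose product inhibits mTORC1, had a log2 ratio of -2.17, and eif4ebp1 was at 220.2 against 314 CPM (log2 ratio -0.49). The lysosomal docking gene lamtor5 was at 604 against 80.5, with a log2 ratio of 2.76 that became 1.28 without its richest cell. The ratio of eif4ebp3l was 1.29 and turned to -0.41 without 1 day 7 cell that held 209 of its 287 UMIs. Amino acid transporters had 2 of 9 measured members higher (median -0.22, percentile 30.3), and amino acid synthesis and ATF4 targets 12 of 17 (median 0.19, percentile 97.0).

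Endothelial cells of day 7 held less RNA of proteasome and heat shock genes than those of day 3. Levels at day 7 against day 3 were 42.1 against 722 CPM for her4.2, 7.22 against 210.5 for her4.3 (29.2-fold lower) and 134 against 1813 for rbp4 (13.6-fold lower). For her4.1 the ratio was 1.63-fold lower, and 360 of its 388 day 7 UMIs lay in 1 cell. Proteasome genes were lower in 34 of 39 cases (median -0.86, percentile 0). Heat shock genes were lower in 32 of 42 (median -0.52, percentile 0.09), with hsp70.1 at 564 against 4518 (8.01-fold lower). Ribosome biogenesis genes were lower in 31 of 44 (median -0.36, percentile 0.78), with mycb 9.79-fold lower. Immediate early genes were lower in 27 of 36 (median -0.53, percentile 0.17), among them the stress gene gadd45ba, 9.72-fold lower. Interferon response genes were lower in 13 of 19 (median -0.54, percentile 0.55). The complement factor D gene cfd was at 1782 against 15816, 8.88-fold lower. The level of nppb was 2.42-fold lower at day 7 than at day 3.

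Matrix and muscle transcripts were higher at day 7 than at day 3 in the endothelial class. Extracellular matrix genes were higher in 25 of 35 cases (median 0.59, percentile 100), although the summed level of the list gave -0.59. The periostin gene postna had 67 UMIs against 0, at least 13.1-fold higher, and the basement membrane collagen gene col4a2 had 73 against 5 (8.59-fold, 3.52 to 27.3). Sarcomere genes were higher in 25 of 27 cases (median 0.95, percentile 100), with actc1a 14.5-fold and gapdh 12.0-fold higher, beside myl7 at 4087 CPM at day 7 and 639.8 at day 3. Nuclear-encoded oxidative phosphorylation genes had a median of 0.29 (percentile 99.9), again not separated from cardiomyocyte RNA. The mTORC1 list stood at -0.29 (percentile 13.2), while its summed level gave 0.88. Amino acid transporters stood at -0.46 (percentile 1.64, 6 of 8 lower) and amino acid synthesis and ATF4 targets at -0.17 (percentile 27.5).

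Single cells also held over 50% of the higher library's UMIs in the comparison of day 7 with day 3, for 8 of the 10 highest and 7 of the 10 lowest genes. Log2 ratios with and without the richest cell were 4.17 and 1.71 for the globin gene ba1, 3.92 and 2.69 for lamtor5, 3.81 and 1.90 for h1f0, 3.74 and 2.62 for fabp3, 3.63 and 1.26 for chd3, 3.53 and 0.92 for gamt, 3.50 and 2.15 for ciarta and 3.48 and 2.33 for gchfr. On the lower side they were -4.52 and -2.71 for arl5c, -4.47 and -2.51 for aplnra, -4.42 and -1.11 for dpp7, -3.91 and -0.97 for elof1, -3.86 and -0.51 for psma6b, -3.74 and -1.99 for errfi1 and -3.70 and -2.05 for cd74b.

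**Figure D3:**
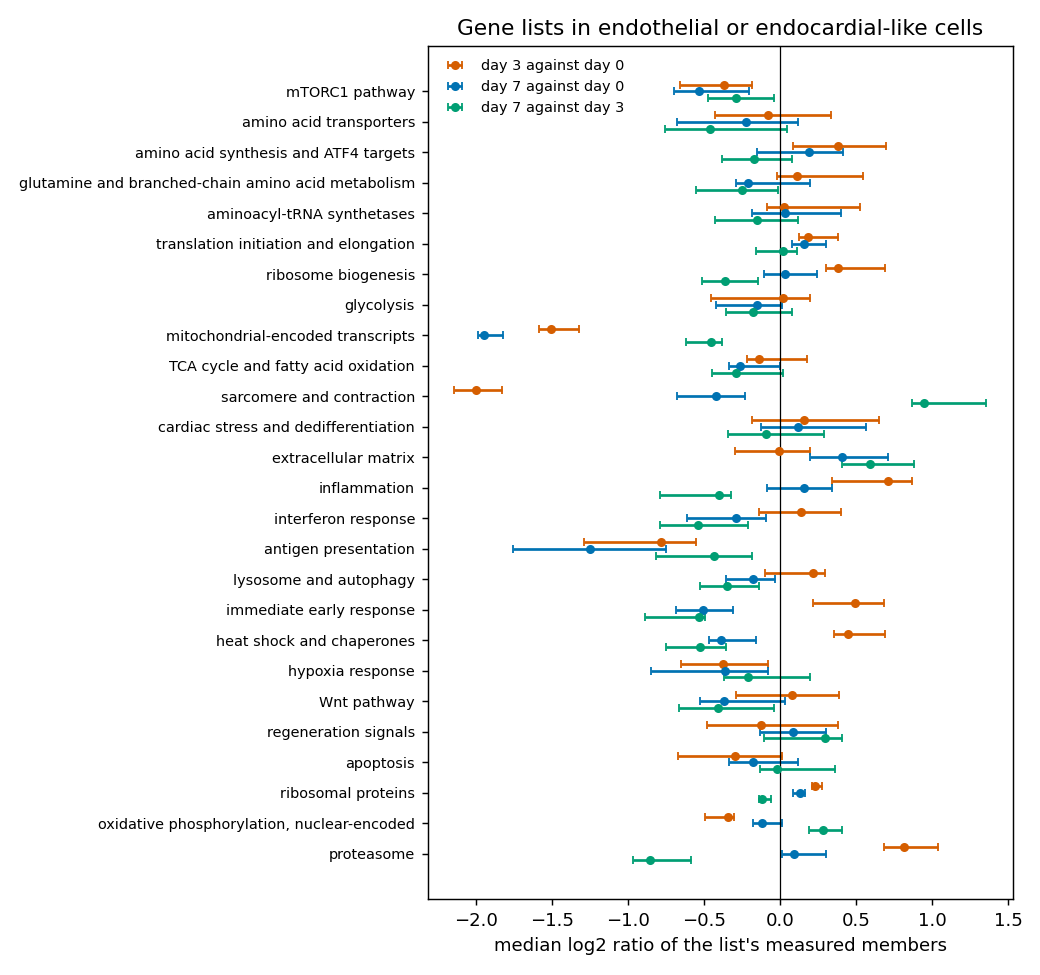
Median log2 ratio of 26 gene lists in the endothelial class for the 3 comparisons of days, with 95% intervals from 200 Poisson draws of the counts. The proteasome list stands at 0.82 for day 3 against day 0 and at -0.86 for day 7 against day 3, and the mitochondrial-encoded list at -1.51 and -1.94 for day 3 and day 7 against day 0.

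Mural cells, the only other class with enough cells to compare, held less matrix RNA at day 7 (61 cells) than at day 0 (88 cells). Extracellular matrix genes were lower in 18 of 22 cases (median -0.77, percentile 0.05). The elastin gene elnb, typical of the outflow tract wall, was at 18.9 against 249 CPM, 13.2-fold lower, and mhc1uba, with 3 UMIs against 57, had a ratio of 0.0747 (0.0150 to 0.230). The antigen presentation list as a whole had 4 of 7 measured members higher in mural cells (median 0.34, percentile 79.2). Without the richest cell of each gene its median was -0.42 (percentile 9). Mitochondrial-encoded transcripts were lower in 13 of 13 cases (median -1.74, percentile 0), ribosomal protein genes in 58 of 81 (median -0.24, percentile 2.44). The mTORC1 list stood at -0.04 (percentile 37.0, 7 of 14 higher). Only 4 amino acid transporters were measured, 3 of them lower (median -2.33, percentile 0), and the median was -1.40 (percentile 0.36) without the richest cell of each gene.

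All of the 10 highest and 8 of the 10 lowest mural ratios had over 50% of the higher library's UMIs in 1 cell. With and without that cell, log2 ratios were 5.04 and 2.24 for mtdha, 4.80 and 2.25 for ube2ib, 4.50 and 3.37 for zgc:158463, 4.25 and -0.16 for uqcc2, 4.16 and 1.88 for chia.6, 4.11 and 3.09 for psmc2, 4.11 and 1.27 for tmem119b, 3.95 and 0.14 for npm3, 3.91 and 0.02 for dgcr6 and 3.89 and 0.72 for txndc9. Lower ones included arrdc3b, with 0 UMIs against 146 (-2.27 without its richest cell), cotl1 (-4.57 and -1.70), sdhaf4 (-3.69 and -2.27), nudcd2 (-3.50 and -0.65), med11 (-3.34 and -1.52), CU019646.2 (-3.08 and -1.45) and slit2 (-3.02 and -2.15).

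Over all cells, differences can come from the mix of classes as well as from levels within them. The part of the mix was examined for day 7 against day 0 only. At day 3 against day 0, nppb was highest (2117 against 25.7 CPM, 82.5-fold, 54.2 to 132) and ckma lowest (16.2 against 686, 42.3-fold lower), with sarcomere genes lower in 27 of 28 cases (median -2.0) and proteasome genes higher in 37 of 39 (median 0.90). Against day 0, day 7 was marked by matrix genes of the fibroblast-like class: postnb had 668 UMIs against 0, at least 141-fold higher, clu 327 against 2 (103-fold, 28.4 to 858), col12a1a 174 against 2 (55.0-fold, 15.0 to 458) and col1a1b was 10.2-fold higher (8.14 to 12.9). Matrix genes were higher in 37 of 46 cases (median 0.80, percentile 100), but with equal weight for each class shared by both days the median was 0.07. Lower at day 7 were elnb (23.7-fold) and mhc1uba (10.3-fold). At day 7 against day 3, postnb had 668 UMIs against 2 (122-fold, 33.5 to 1007), fn1b was 30.2-fold, actc1a 25.4-fold and gapdh 18.4-fold higher, and the flow-responsive gene klf2a had a log2 ratio of -3.40, which was -2.64 without its richest cell. All of the 10 lowest genes of that comparison had over 50% of their day 3 UMIs in 1 cell, and 0 of them were among the 10 lowest without the richest cell. Sarcomere and matrix lists had medians of 1.40 and 1.2 for that comparison.

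Counts of the genes fixed for the question of amino acids and mTOR were low over all cells. The leucine transporter gene slc7a5 had 0 UMIs in every library, which allows up to 3.50, 6.08 and 2.21 CPM at day 0, 3 and 7, and slc43a2b also had 0. Its partner slc3a2a had 0, 1 and 3 UMIs, and no slc3a2b was listed. The UMIs at day 0, 3 and 7 were 10, 9 and 11 for slc38a2, 3, 0 and 0 for slc43a1b, 6, 2 and 9 for mtor, 6, 0 and 3 for rptor, 7, 1 and 6 for rheb, 0, 1 and 6 for asns, and 5, 16 and 9 for glula. A difference in these genes was not detectable at this depth, apart from glula, which was 5.56-fold higher at day 3 than at day 0 (1.95 to 19.4) and at day 7 had 0.205 times its day 3 level (0.0798 to 0.492). Transcripts of sesn1 numbered 180, 13 and 43, with 119 of the day 0 UMIs in 1 cardiomyocyte-like cell. The ventricular myosin gene vmhc had 0, 0 and 41 UMIs and nppa, the atrial natriuretic peptide gene, 11, 4 and 20. The retinoic acid enzyme gene aldh1a2 was at 152, 357 and 172 CPM.

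Transcripts of cycling cells were found in most cells of every library. After thinning, a UMI of any of 24 cycling markers was present in 92.2%, 87.6% and 83.5% of endothelial cells at day 0, 3 and 7, and in 85.2% and 78.7% of mural cells at day 0 and day 7, so the endothelial shares lay near those of another class. The widely expressed hmgb2a, hmgn2 and tuba8l filled this measure. With only the 21 markers found in at most 10% of cells, a choice made after seeing the data, endothelial shares were 8.43% (4.69 to 13.7), 20.4% (13.4 to 29.0) and 15.2% (10.7 to 20.6), and mural shares 7.95% and 4.92%. The proliferation gene mki67 had 2, 2 and 10 UMIs over all cells. For pcna, a replication clamp gene, 156 of 179 day 3 UMIs lay in 1 cell, and its endothelial log2 ratio at day 3 against day 0 was 2.77 with that cell and 0.42 without it.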

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

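The tests of this part were chosen after the results were seen, and the gene lists were fixed before the data were examined.

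Extracellular matrix genes were higher at day 7 than at day 0 in endothelial cells and lower in mural cells. The median log2 ratio was 0.41 over 37 measured genes in endothelial cells and -0.77 over 22 measured genes in mural cells. The opposite directions of the same comparison in the 2 classes drew attention to it, and the difference between the classes was not tested. By marker score, 31 of the 224 endothelial-class cells of day 7 were highest for fibroblast markers, against 3 of 166 at day 0, so the endothelial value was not separated from such cells. Each value came from 1 library per day.

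Nearly all cells of the day 3 library belonged to the endothelial class. Misplacement of other cells in endothelial clusters would have left their markers in the library. The summed mural marker level of day 3 was 0.185 times that of day 0 (0.167 to 0.204). This argues against misplacement of as large a share of mural cells as day 0 held, but does not exclude a smaller one. Cluster 6, with 34 of its 36 cells from day 3, had a mural sum of 1665 CPM, against 456, 347 and 437 in clusters 0, 2 and 3. Misplacement also stays open for epicardial cells and macrophages. The summed epicardial marker level of day 3 was 2.73 times that of day 0 (2.52 to 2.97), with 3 of 7 detected markers higher and krt15 giving 2457 of 2992 CPM. In cluster 6 the epicardial sum was 6331 CPM, against 770, 908 and 751 in clusters 0, 2 and 3. The macrophage level was 2.65 times that of day 0 (2.28 to 3.09), with 12 of 13 detected markers higher, most of them at few UMIs, and 191 of 257 cd74b UMIs in 1 cell. In cluster 3, with 60 of its 88 cells from day 3, the macrophage sum was 1329 CPM. It was 354, 447 and 307 in clusters 0, 2 and 6. Digestion or capture of the day 3 library, the drug and the injury at day 3 cannot be told apart, since there was 1 library at day 3.

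Transcripts encoded by the mitochondrial genome were lower at day 3 and day 7 than at day 0. A different mix of cell classes would leave the levels within classes alike, but the highest of the within-class medians against day 0 was -1.51 (-1.58 to -1.32), which argues against it. More free cardiomyocyte RNA at day 0 stays open for endothelial cells. In cardiomyocyte-like cells themselves, mitochondrial-encoded transcripts made up 7.97% of pooled UMIs at day 0 (18 cells) and 2.34% at day 7 (30 cells). In mural cells they made up 2.12% and 0.658%. Mural myl7 was at 1888 CPM at day 0 and 1575 at day 7, against 66585 in cardiomyocyte-like cells of day 0. This argues against free RNA with the makeup of those cells as the whole source in mural cells. The makeup of free RNA was not measured, so a source richer in mitochondrial transcripts stays open there. The mitochondrial median differed from the sarcomere median by -1.78 (-2.32 to -1.16) in mural cells at day 7 and by -1.53 (-1.76 to -1.14) in endothelial cells at day 7. In cardiomyocyte-like cells, the source of such RNA, it differed by -2.19 (-2.90 to -1.34), so these differences do not decide. In endothelial cells at day 3 the difference was 0.49 (0.25 to 0.82), and no cardiomyocyte-like cells were found on that day. The injury, the metronidazole given before it and the library cannot be told apart with 1 library per day and no drug listed for day 0.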

How the results depend on the processing

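Alternatives without the richest cell of each gene or the deepest day 3 cell, the coarser clusters and the cycling markers found in few cells were chosen after the data were seen. The cause was not tested for any of the values below, unless stated.

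A gene ratio was called if its interval left out 0, and only called ratios could count as changed. Genes with 0 UMIs in either library were never called, since their intervals have an open end. Another pseudocount cannot change the sign of a gene ratio, so those alternatives could not count against it. For the 129 gene ratios named, 980 of 982 alternative values brought no change of sign of a called ratio. The 2 that did were without the richest cell: eif4ebp3l at day 7 against day 0 in endothelial cells (-0.41) and uqcc2 in mural cells (-0.16). For 88 list medians this held for 844 of 848 values. A pseudocount of 50 CPM moved 105 gene ratios beyond their counting interval, and leaving out the richest cell moved 72. Leaving out the deepest day 3 cell moved 5 of them and 0 list medians.

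With cells assigned to their highest marker score, endothelial shares were 30.9%, 31.6% and 17.7% at day 0, 3 and 7, cardiomyocyte shares 18.0% and 17.12% at day 0 and 7, and fibroblast shares 1.84% and 21.5%. With at least 2 cycling markers, shares were 54.2%, 54.9% and 41.1% in endothelial cells and 31.8% and 24.6% in mural cells. Without thinning, endothelial shares were 96.5% at day 3 and 89.7% at day 7. With cycling markers found in at most 10% of cells, they were 8.43%, 20.4% and 15.2%, and 7.95% and 4.92% in mural cells.

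The summed level of a list follows its most abundant members. For day 3 against day 0 in endothelial cells it gave -0.83 for the mTORC1 pathway, 0.99 for amino acid synthesis, 1.89 for matrix (opposite in sign to the median of -0.01) and 1.67 for the proteasome. For day 7 against day 0 it gave 0.0386 for the mTORC1 pathway (reversed), -1.05 for amino acid transporters, 1.29 for matrix and 0.0640 for heat shock (reversed). For day 7 against day 3 it gave 0.88 for the mTORC1 pathway (opposite in sign to the median of -0.29), -0.83 for transporters, -1.11 for amino acid synthesis, -0.59 for matrix (reversed) and -1.37 for the proteasome.

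With members detected in at least 5% of cells, medians were 0.52 for transporters at day 3 against day 0 (opposite in sign to -0.08), -0.77 for the mTORC1 pathway and 0.77 for matrix at day 7 against day 0, and -0.41 for amino acid synthesis at day 7 against day 3. A pseudocount of 1 gave 0.72 for amino acid synthesis at day 3 against day 0, -0.77 for the mTORC1 pathway at day 7 against day 0, and 0.97 for matrix and -1.12 for the proteasome at day 7 against day 3. A pseudocount of 50 gave 0.48 for the proteasome at day 3 against day 0, and 0.23 for matrix and -0.46 for the proteasome at day 7 against day 3. Thinned cells gave proteasome medians of 1.04 at day 3 against day 0 and -0.97 at day 7 against day 3. The mean over cells gave -0.00708 for the proteasome at day 7 against day 0 (reversed) and -1.10 at day 7 against day 3.

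Over all cells, with a filter of 5% of cells, 6 of the 10 highest and 8 of the 10 lowest genes of day 3 against day 0 were shared, 7 and 5 of day 7 against day 0, and 8 and 6 of day 7 against day 3. With a filter of 5 cells only, the shared genes were 4 and 4, 4 and 0, and 7 and 2. Equal weight for each class was run for day 7 against day 0 only, since day 3 lacked classes, and left out fibroblast-like cells, which day 0 lacked. It moved all 6 gene ratios and the 1 list median. The matrix median went from 0.80 to 0.07, and log2 ratios from 5.65 to 2.32 for postnb, 4.35 to 1.85 for clu, 3.49 to 0.77 for col12a1a, 3.22 to 1.00 for col1a1b, -2.99 to -2.60 for mhc1uba and -2.83 to -2.25 for elnb. The minimum of 200 genes removed no cell and says nothing about stability.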

Other observations

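The tests in this part were chosen after the results were seen.

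Transcripts of the myoglobin gene mb were abundant in the endothelial class. At day 0 its level was 28362 CPM in endothelial cells, 1619 in mural cells and 23759 in cardiomyocyte-like cells. Free cardiomyocyte RNA would bring mb and myl7 in 1 ratio to every class. At day 0 there were 2.88 UMIs of mb per UMI of myl7 in endothelial cells, 0.857 in mural cells and 0.357 in cardiomyocyte-like cells. The ratio of endothelial to mural cells was 3.36 (2.97 to 3.81), which argues against free RNA as the whole source. The ratio of endothelial to cardiomyocyte-like cells was 8.08 (7.49 to 8.71), which argues against doublets with these cells as the whole source. No biological explanation was tested.

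Many genes had a single cell far richer in their UMIs than any other. In 462 genes, 1 cell held at least 50 UMIs and at least 5 times those of the next cell. These lay in 331 cells, with a median of 134 UMIs against 5 in the next cell, and made up 2.701% of all UMIs. There were 48.2 such cases per 100 cells at day 0, 78.1 at day 3 and 65.8 at day 7. Median UMIs per cell were 2677, 3260.5 and 3124.5, and these rates were not corrected for depth. Cells with 2 or more such cases numbered 102, against a median of 98 (87 to 109) in 1000 random assignments weighted by the UMIs of each cell.

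Cardiomyocyte-like cells numbered 18 at day 0 and 30 at day 7, and a comparison required 20 in both libraries. In them vmhc had 35 UMIs at day 7 against 0 at day 0, and mt-co2 stood at 894 against 6891 CPM.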
